A study of Homo sapiens with 4 samples.

How the data were processed

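The series holds 4 arrays of U87 cells, 2 with negative control shRNA and 2 with NUP107 shRNA, all taken 7 days after lentivirus infection. Per the labels, total RNA was labelled with Cy3 and each array carries 1 sample. Spot intensities were produced with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. Per the file headers, the processed signal is a background-subtracted, detrended intensity with no scaling between arrays, and the 4 arrays lay on 1 slide and were scanned in 1 scan, so no slide or scan block could be fitted. The deposited value table holds a linear ratio, which a comparison with the scanner files showed to be the processed signal divided by the 75th percentile of its array (all of 24176 matched probes within 1%), with column medians from 0.329 to 0.339. Neither the filter behind its 24194 probes nor the reason for it is given in the sources used here. Other deposited columns used were flags of 0 or 1 per spot and, for the normexp alternative, the median spot and background signals.

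Each array has 44495 spots, of which 43118 are not controls. Spots flagged as non-uniform or as population outliers were left out, and the rest were averaged per probe, which left 34087 of 34127 probes after 40 had been dropped. No probe was saturated. The files name no gene, so probes were named by the RefSeq accession in their systematic name, without versions, through a RefSeq gene table (assembly GRCh38.p14). Of 26569 probes with an NM or NR accession 25741 were named, as were 2 probes with another accession in the table, so that 25743 probes received 1 symbol (19724 genes) while 8344 stayed unnamed. The header names another assembly, so the table was used for names alone and no coordinates are printed.

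The main setting was log2 of the processed signal minus the 75th percentile of its array. Probes were kept where they were well above background on both arrays of at least 1 group, and each gene was represented by its kept probe with the highest mean over all 4 arrays. This left 14301 genes, tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, group as the sole term, Benjamini-Hochberg adjusted p under 0.05). SE is limma's moderated standard error, with 2 residual and 2.53 prior degrees of freedom. A gene not well above background on either array of a group has a lower bound in place of a fold. The bound sets the mean of the brighter group against, per dim array, the higher of the lowest signal well above background and the signal of the probe itself, and no fold is given where this is under 1. The lowest signal is taken over all probes of the array, so it is not a detection limit of the single probe. Where the probe's own signal is the higher, the bound equals the fitted fold. For 59 genes the control group and for 224 the NUP107 shRNA group was not well above background. Among 4038 tested probes without a symbol, 524 were higher and 382 lower when every probe was tested.

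Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule takes NUP107, MDM2, CDKN1A, MDM4 and the Y-complex genes always, then the 15 highest and 15 lowest fold changes among called genes whose arrays do not overlap between groups, and up to 4 members of each list described, by adjusted p. Names that are not gene symbols were skipped, and a few genes that the rule takes are not reported here. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with an estimated correlation. Limma's fry tested each list against no change of its own members, without reference to other genes. With the preset correlation 10 lists were called, 7 upward and 3 downward. With an estimated correlation camera called 0, at an unadjusted p under 0.05 also 0, with 0.059 as the smallest p, and fry called 1 list (inflammatory genes) for balance of direction and 28 for change in either direction. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so its loss of calls does not measure correlation alone. Its unadjusted p also rose for lists with an estimated correlation under 0.01, from 0.11 to 0.23 for neural stem and from 0.10 to 0.21 for cholesterol genes.

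Replicate arrays of a group correlated at 0.998 (control) and 0.996 (NUP107 shRNA) across probes, which are not independent replicates. Per the labels the arrays are biological replicates, and each was counted as 1. The first principal component held 85.0% of the variance. Alternatives were a normexp background with an offset of 50, quantile, array median and spike-in scales, other filters, other rules for probes, intensity trend, robust or no variance moderation, a threshold of 0.1, treat against a fold of 1.2, a replicate block, the deposited value table, and leaving out each array in turn. The files hold no mean signal column, so normexp ran on the median spot and background signals in place of the planned mean signals. Spike-in scaling used the 7 of 10 control probes well above background on all arrays.

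The tests were checked on simulated data before use. Over 20 simulated sets of 14301 genes with the real means and limma's moderated spreads, 200 genes were changed per set. Calls recovered 32.8% of genes changed by 0.5 on the log2 scale, 94.9% of those changed by 1 and 99.3% of those changed by 2, and 7.38% of calls were false, above the nominal 5%. A shift of 0.2 given to the p53 list was called in 20 of 20 sets, and in 0 of 20 without it. The noise was drawn independently for each gene, so these counts do not give the false-call rate of lists whose members vary together. In the data the p53 list had an estimated correlation of 0.24. Random lists matched on signal drew, for each member, 1 of the 50 genes outside the list nearest in mean signal, 10000 times. This matching replaced a coarser one by signal bins, and the intervals around a list or probe median were added, after first values had been seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The hairpin sequences, the number of hairpins and the position of the NUP107 probe are not given in the sources used here.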

Results

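Gene expression was measured in U87 cells, an established human glioblastoma line, on 1-colour Agilent oligonucleotide arrays. Cells infected with a lentivirus carrying an shRNA against NUP107 were compared with cells infected with a negative control virus, 7 days after infection, with 2 arrays in each group. NUP107 encodes a scaffold subunit of the Y-complex, the outer ring of the nuclear pore. The title of the series names nuclear pores and p53, so the comparison asks which transcripts, p53 target genes among them, differ after NUP107 knockdown. Of 34127 probes, 69.2% and 66.0% were well above background on the control arrays and 66.2% and 61.9% on the NUP107 shRNA arrays. The 75th percentile of the processed signal was 874 and 876 on the control arrays and 590 and 563 on the NUP107 shRNA arrays. The labels call the arrays biological replicates without describing the cultures, so p-values here measure the spread between these arrays, and their small number limits the precision.

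NUP107 itself was lower in both knockdown arrays than in both control arrays. Its log2 signal relative to the 75th percentile of the array was 3.17 and 3.22 with control shRNA and 2.47 and 2.32 with NUP107 shRNA. The log2 fold change was -0.80 (SE 0.08, n = 2 arrays per group, limma's adjusted p = 0.0081), which left 57.6% of the control level on the single probe of the gene. Among the 9 other Y-complex genes tested, SEH1L fell by 0.45 and NUP37 fell by 0.33 on the log2 scale (limma's adjusted p = 0.027 and 0.033). The other 7 did not pass the test, with values from -0.23 for NUP85 to 0.28 for SEC13, and adjusted over the list alone the count was also 2 lower. A second AHCTF1 probe was at 0.49 and passed upward (adjusted p over all probes = 0.035), with the brightest at -0.07. A second SEH1L probe gave -0.05, and with the mean of its probes SEH1L did not pass (adjusted p = 0.059). Without control replicate 1 the NUP107 fall had an adjusted p of 0.076, and without control replicate 2 one of 0.082, with log2 fold changes of -0.82 and -0.77. SEH1L and NUP37 also no longer passed without either control array, with adjusted p values of 0.14 and 0.16 for SEH1L and of 0.16 and 0.20 for NUP37, and NUP37 did not pass without NUP107 shRNA replicate 2 (adjusted p = 0.067).

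Of 14301 genes tested, 2408 were higher and 2209 were lower with NUP107 shRNA (limma, Benjamini-Hochberg adjusted p under 0.05). The large changes ran upward, with 512 genes up and 96 down by more than 2-fold, and 134 up and 3 down by more than 4-fold, with lower bounds in place of folds that could not be measured. Among the 15 named genes with the highest fold changes, INHBA, which encodes a subunit of the growth factor activin, was 51.4-fold higher, although only 1 of the 2 control arrays measured it above background. SCG2, a granin of secretory vesicles, rose 42.0-fold, MGP, a matrix protein that inhibits calcification, 30.6-fold, and IGFBP1, a binding protein of insulin-like growth factors, 17.2-fold. SERPINB2, a plasminogen activator inhibitor, rose 16.4-fold and CXCL1, a neutrophil chemokine, 16.7-fold on its brightest probe. On the log2 scale that CXCL1 probe gave 4.07, and another gave 2.07. CXCL8, another neutrophil chemokine, was at least 6.99-fold higher, TNFSF14, a cytokine of the TNF family, at least 5.75-fold, and the matrix protein gene EFEMP1 at least 9.38-fold, since the control arrays did not measure them well above background. The small heat shock protein gene HSPB3 and ODAPH were in the same way at least 17.3-fold and at least 11.03-fold higher. PLA2G2F, a secreted phospholipase, was 20.7-fold higher with 1 of the 2 control arrays above background.

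Probes of 1 gene did not always move together among these genes. PKD1L2 was at least 18.6-fold higher on its brightest probe, and another probe gave a log2 fold change of -0.47 (adjusted p over all probes = 0.092). MIEF1, which encodes a mitochondrial dynamics protein, was 17.7-fold higher on its brightest probe, with 0.04 and 0.05 on the log2 scale on its other probes. RNA5-8SN5, a copy of the repeated 5.8S ribosomal RNA gene, gave a log2 fold change of 4.78 on a probe that cannot tell the copies apart. Over all called genes, 77.6% of 1340 further probes had the sign of the brightest probe, 429 passed in the same direction and 63 in the opposite one.

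The genes with the deepest falls included RAD1, a subunit of the DNA damage checkpoint clamp, which fell by 2.54 on the log2 scale (SE 0.07, n = 2, limma's adjusted p = 0.0013) on its brightest probe and gave -0.11 on another. ABCB5, a membrane transporter, gave -2.61 with 1 of the 2 NUP107 shRNA arrays above background, and its other probe gave -0.24. The proton channel gene OTOP1 fell by 2.53, PIAS1, a SUMO ligase, by 1.84, SH2D1A, a lymphocyte adaptor, by 1.80 and CCDC172 by 1.53. ECHDC3 gave -1.56 with 1 of the 2 NUP107 shRNA arrays above background. The NUP107 shRNA arrays did not measure the remaining 8 well above background. TGM6, LRP1B, TMEM244 and GPR142 were at least 1.15-fold, 1.81-fold, 1.5-fold and 1.22-fold lower, while FAM226A, LUZP4, COL4A4 and OR8B3 allowed no fold. Under a normexp background, whose offset alone gives a probe without signal 0.56, these 8 dim genes and ECHDC3 had the opposite sign, with values from 0.04 for ECHDC3 to 0.40 for FAM226A.

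The counts rested on both control arrays and on the scale. Without control replicate 1, 222 genes were higher and 39 lower, and without control replicate 2, 195 and 36, and no variance moderation left 1 gene in each direction. Calls were 52.2% upward with the 75th percentile, 30.8% with the array median (1638 higher, 3673 lower), 22.0% with spike-in probes (1197 higher, 4239 lower), 66.9% with a normexp background (5434 higher, 2691 lower) and 76.1% with no filter on dim probes (332 higher, 104 lower), so that fold changes here are relative to the 75th percentile. The groups did not overlap for 10586 genes (74.0%, against 33.3% by chance), and an exact permutation test of 2 against 2 arrays cannot give a p under 0.333.

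Genes that p53 activates moved upward as a group. Of 80 tested members of the fixed list, 40 rose, 3 fell and 37 did not pass, and adjusted over the list alone 41 were higher and 3 lower. The median log2 fold change was 0.35 (limma's camera, adjusted p = 4.8e-07 over 29 lists with a preset correlation, adjusted p = 0.79 with an estimated correlation). PLK2, a polo-like kinase, rose 13.5-fold, GDF15, a stress-induced secreted factor, 5.79-fold, and ANKRA2 2.18-fold. CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, had a log2 fold change of 1.70 (SE 0.24, n = 2, limma's adjusted p = 0.014). MDM2, the ubiquitin ligase that limits p53, had one of 0.93 (SE 0.07, n = 2, limma's adjusted p = 0.0043), and its other probes gave 1.34 and 1.42. The members that fell were RAP2B, PERP and STEAP3, named after their values were seen, at -0.90, -0.75 and -0.42. MDM4, which encodes a relative of MDM2, was at 0.13 (adjusted p = 0.27) and did not pass, although with a normexp background it did (0.20, adjusted p = 0.039), and scaled to spike-in probes it was at -0.07. The count of 40 fell to 2 without either control array, where MDM2 and CDKN1A also lost their calls (adjusted p = 0.057 and 0.092 without replicate 1, 0.061 and 0.099 without replicate 2), while scaled to spike-in probes 21 members were higher and 8 lower, and the median was 0.15.

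**Figure D1:**
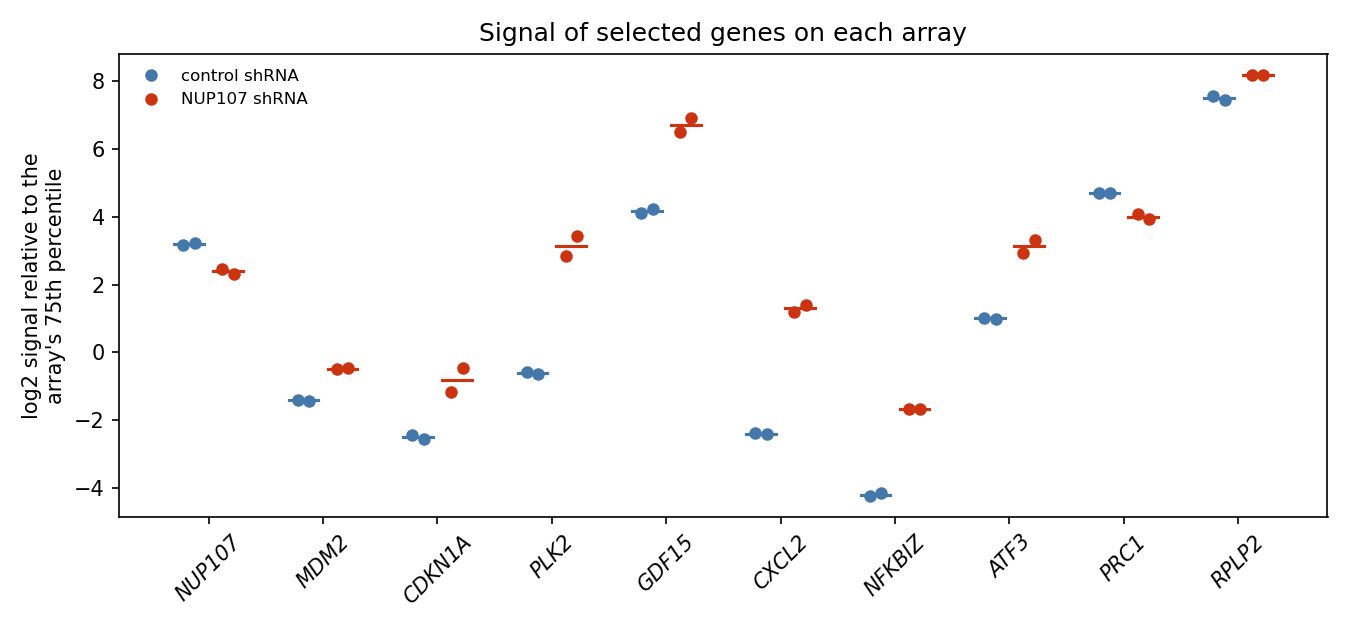
Log2 signal relative to the 75th percentile of the array (vertical axis) for 10 genes (horizontal axis) on each array, with control shRNA in blue and NUP107 shRNA in red. Points are the 2 arrays of a group and lines their mean. NUP107 and PRC1 lay lower on both NUP107 shRNA arrays, and MDM2, CDKN1A, PLK2, GDF15, CXCL2, NFKBIZ, ATF3 and RPLP2 higher, by 3.75 on the log2 scale for PLK2.

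Inflammatory and NF-kB genes gave the highest median of the lists. Of 30 tested members, 28 rose, none fell and 2 did not pass (29 higher adjusted over the list alone), with a median log2 fold change of 1.80, or 1.69 with 3 members set to their lower bounds (limma's camera, adjusted p = 1.3e-17, and adjusted p = 0.79 with an estimated correlation). The chemokine genes CXCL2 and CXCL3 rose by 3.70 and 3.27 on the log2 scale, and NFKBIZ, a nuclear regulator of NF-kB, by 2.52. IL33 and NFKB1 were the members that did not pass, named after their values were seen, at 0.48 and 0.17. Without control replicate 1, 18 members were higher, and without control replicate 2, 19. Immediate early genes, which growth and stress signals induce within minutes, held 13 members that rose and 2 that fell of 27 tested (15 and 2 adjusted over the list alone), with a median of 0.46 (limma's camera, adjusted p = 3.2e-04, and adjusted p = 0.79 with an estimated correlation). EGR2 rose 3.86-fold, IER3 2.83-fold, the growth factor gene EREG 4.81-fold and the MAP kinase phosphatase gene DUSP4 2.00-fold. KLF2 at -0.49 and EGR1 at -0.35, named after their values were seen, fell, without either control array 1 member was higher, and the median was 0.25 under the spike-in scale.

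Cell cycle genes were lower. Of 56 genes of the G1/S transition and DNA replication, 28 fell, none rose and 28 did not pass (37 lower adjusted over the list alone), with a median log2 fold change of -0.31 (limma's camera, adjusted p = 9.5e-10, and adjusted p = 0.79 with an estimated correlation). DTL, an adaptor of a ubiquitin ligase active in S phase, fell by 0.62 on the log2 scale, the primase subunit gene PRIM2 by 0.59 and the replicative helicase gene MCM6 by 0.45. Of 65 genes of G2 and mitosis, 18 fell, none rose and 47 did not pass (18 lower adjusted over the list alone), with a median of -0.33 (limma's camera, adjusted p = 1.1e-07, and adjusted p = 0.79 with an estimated correlation). The estimated correlation was 0.75 for the mitosis list, the highest of the 29 lists, and 0.50 for G1/S, against the preset 0.01. The mitosis list was the one that fry did not call for change in either direction (fry, adjusted p = 0.056, and 0.16 for balance of direction). PRC1, a midzone microtubule protein, fell by 0.69, the centromere gene CENPM by 0.73, CEP55, an abscission factor, by 0.70 and the mitotic transcription factor gene FOXM1 by 0.41. No member of either list passed without either control array, and under the spike-in scale 47 and 56 were lower, with medians of -0.51 and -0.53, and 46 and 37 under the array median. Without NUP107 shRNA replicate 1, 50 of the mitosis genes were lower and 1 was higher, with a median of -0.47, and without NUP107 shRNA replicate 2 the medians were -0.19 for mitosis and -0.27 for G1/S, where 16 were lower.

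Replication-dependent histone genes, whose transcripts normally lack a poly(A) tail, moved both ways, mostly downward. Of 54 tested, 25 fell, 6 rose and 23 did not pass (31 lower and 10 higher adjusted over the list alone), with a median of -0.41 (limma's camera, adjusted p = 0.0086, and adjusted p = 0.79 with an estimated correlation). H3C11 fell by 0.74 and H2BC3 by 0.55, while H2AC7 rose 2.69-fold. H4C16 was at -0.99, and at 0.08 under the normexp background. None of the list passed without either control array, and without NUP107 shRNA replicate 1, 33 were lower and 10 higher. With the deposited values, 8 were lower and 4 higher, at a median of -0.41.

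Cytosolic ribosomal protein genes showed a small joint rise. Of 78 tested, 35 rose, none fell and 43 did not pass (42 higher adjusted over the list alone), with a median log2 fold change of 0.27 (limma's camera, adjusted p = 4.1e-09, and adjusted p = 0.79 with an estimated correlation). RPL31 rose 1.65-fold, RPLP2 1.59-fold and RPLP1 1.55-fold. RPS2 rose 1.57-fold on its brightest probe, with 0.04 and -0.12 on the log2 scale on its other probes, and did not pass with their mean (adjusted p = 0.096). The size depended on the scale, with medians of 0.15 under the array median, 0.08 under quantile normalization (11 higher, 1 lower) and 0.07 under spike-in probes (5 higher). No member passed without either control array.

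Genes of the unfolded protein and integrated stress responses moved upward, with 17 of 40 higher, 2 lower and 21 not passing (19 higher and 3 lower adjusted over the list alone) and a median of 0.29 (limma's camera, adjusted p = 6.2e-04, and adjusted p = 0.79 with an estimated correlation). ATF3, a stress-induced transcription factor, rose 4.32-fold, DDIT4, an inhibitor of mTORC1 signalling, 3.54-fold, the secreted glycoprotein gene STC2 2.57-fold and ALDH1L2, a mitochondrial folate enzyme, 1.72-fold. One ATF3 probe of 4 gave -0.11, against 1.81 to 2.11 on the others. The brightest SEL1L probe was lower, and its other probes gave -0.89 and 0.04 (adjusted p over all probes = 0.069 and 0.74). SEL1L and CRELD2, named after their values were seen, fell by 0.49 and 0.41, and the count of higher members was 1 without control replicate 1 and 0 without control replicate 2. Without NUP107 shRNA replicate 1, 20 were higher and 4 lower, under the array median 12 and 4 (median 0.17), and under the spike-in scale 7 and 4 (median 0.09).

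Extracellular matrix and mesenchymal genes held 18 members that rose, 4 that fell and 25 that did not pass of 47 tested (20 higher and 7 lower adjusted over the list alone), with a median of 0.33 (limma's camera, adjusted p = 0.0081, and adjusted p = 0.79 with an estimated correlation). The proteoglycan genes DCN and VCAN rose 3.85-fold and 3.93-fold, BGN was at least 3.64-fold higher, and TGFBI, a matrix adaptor induced by TGF-beta, rose 2.33-fold. CHI3L1, ZEB1, COL6A2 and FBLN5, named after their values were seen, fell by 0.81, 0.38, 0.34 and 0.59. The list was not called under the normexp background (adjusted p = 0.084), had 18 higher and 9 lower members under the array median (median 0.21) and 15 and 11 under the spike-in scale (median 0.13), and 3 higher and no lower members without either control array. Without NUP107 shRNA replicate 2 its median was 0.16, with 18 higher and 8 lower, and without NUP107 shRNA replicate 1 it had 21 higher and 7 lower.

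Hypoxia and glycolysis genes held 13 members that rose, 4 that fell and 19 that did not pass of 36 tested (16 higher and 4 lower adjusted over the list alone), with a median of 0.23 (limma's camera, adjusted p = 0.026, and adjusted p = 0.87 with an estimated correlation). CA9, a carbonic anhydrase at the cell surface, rose 12.8-fold, ANGPTL4 2.36-fold, the histone demethylase gene KDM3A 2.14-fold and hexokinase HK2 1.61-fold. The members that fell, named after their values were seen, were the glycolytic enzyme genes PFKL, PFKP, ENO2 and HK1, at -0.75, -0.49, -0.31 and -0.27. The list was not called without NUP107 shRNA replicate 2 (median 0.14, adjusted p = 0.16), under the normexp background (adjusted p = 0.40) or with no filter (adjusted p = 0.22), and 1 and 2 members were higher without control replicates 1 and 2. Its median was 0.39 without NUP107 shRNA replicate 1 (19 higher, 2 lower), 0.10 under the array median (10 higher, 6 lower) and 0.03 under the spike-in scale (8 higher, 5 lower).

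Several lists close to the question were not called in the main setting. Since 32.3% of all genes tested were called, single called members do not set a list apart. Of 21 other nucleoporin genes, NUP50 and NUP205 fell by 0.70 and 0.30 and 19 did not pass (1 lower adjusted over the list alone, camera adjusted p = 0.20), but another NUP50 probe rose by 0.54 (adjusted p over all probes = 0.021). Of 32 nuclear transport receptor and Ran system genes, the importin genes KPNA5 (0.97) and KPNA7 (at least 2.50-fold) and the mRNA export factor gene NXF1 (0.51) rose, NXT1 fell by 0.35 and 28 did not pass (3 higher adjusted over the list alone, camera adjusted p = 0.76). Among 28 apoptosis regulators, BIRC3 (2.36), BMF (at least 10.8-fold), BID (0.77) and PMAIP1 (0.57) rose, and CASP6, MCL1, BCL2L1 and TRADD, named after their values were seen, fell by 0.59, 0.36, 0.43 and 0.34 (4 each way adjusted over the list alone, camera adjusted p = 0.76). For BMF, not well above background on the control arrays, the bound equals the fitted fold. Of 46 interferon-stimulated genes, 8 rose, among them BST2 (1.84), IRF1 (1.03) and ISG20 (0.68), and 7 fell, among them the RNA sensor gene RIGI, by 0.89 (8 and 7 adjusted over the list alone, camera adjusted p = 0.82). Of 48 DNA damage signalling and repair genes, 11 fell, among them the Fanconi anaemia genes FANCC by 0.78 and FANCL by 0.50, and LIG4 (0.55), MDC1 (0.31), RAD17 (0.32) and RAD9A (0.34) rose, the last 3 named after their values were seen (4 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.20). Of 27 YAP/TAZ and TGF-beta target genes, 12 rose, among them the kinase gene NUAK2 (1.55), SKIL (0.82), SMAD7 (1.11) and AMOTL2 (0.62), and TGFBR1, PMEPA1, TEAD1, DLC1 and SMAD6, named after their values were seen, fell by 0.75, 0.51, 0.41, 0.31 and 0.50 (14 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.093). PMEPA1 was at 0.00 under the normexp background. Of these genes, BIRC3, BST2 and NUAK2 still passed without either control array.

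The calls and counts of these lists moved with the arrays and the scale as well. The YAP/TAZ and TGF-beta list was called under quantile normalization (adjusted p = 0.039), the array median (0.017) and the spike-in scale (0.0062), and without NUP107 shRNA replicate 1 (0.038). The DNA repair list was called with a normexp background (adjusted p = 0.011), with no filter (0.014) and with every probe on its own (0.041), and the nucleoporin list with a normexp background (0.031) and with no filter (0.0495). The median of all genes was -0.01 in the main setting, 0.09 with normexp and 0.10 with no filter. In the same order, list medians were -0.115, -0.093 and -0.115 for DNA repair and -0.113, -0.106 and -0.095 for other nucleoporins. The calls under normexp and no filter thus show no deeper fall of these lists. Without either control array the apoptosis and interferon lists held 1 higher gene each, the DNA repair list 1 lower gene, the YAP/TAZ and TGF-beta list 3 and 2 higher genes, and the nucleoporin and transport lists none. Without NUP107 shRNA replicate 1, 5 nucleoporin genes were lower, and 4 transport genes were higher and 3 lower. Without NUP107 shRNA replicate 2, 1 nucleoporin gene and 1 Y-complex gene were lower, and 1 DNA repair gene was higher and 10 lower. Higher and lower counts under the spike-in scale were 3 and 7 for apoptosis regulators, 4 and 14 for interferon-stimulated genes, 0 and 21 for DNA repair genes, 2 and 4 for transport genes, 0 and 8 for other nucleoporins, 0 and 3 for Y-complex genes and 9 and 7 for YAP/TAZ and TGF-beta targets. Under the array median they were 5 and 11 for interferon-stimulated genes, 1 and 18 for DNA repair genes and 0 and 7 for other nucleoporins, and under the normexp background 15 and 8 for interferon-stimulated genes and 0 and 6 for other nucleoporins. The medians of apoptosis, interferon and transport genes turned from 0.05, 0.03 and 0.02 to -0.15, -0.17 and -0.18 under the spike-in scale, and those of other nucleoporins and Y-complex genes moved from -0.11 and -0.07 to -0.32 and -0.27.

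**Figure D2:**
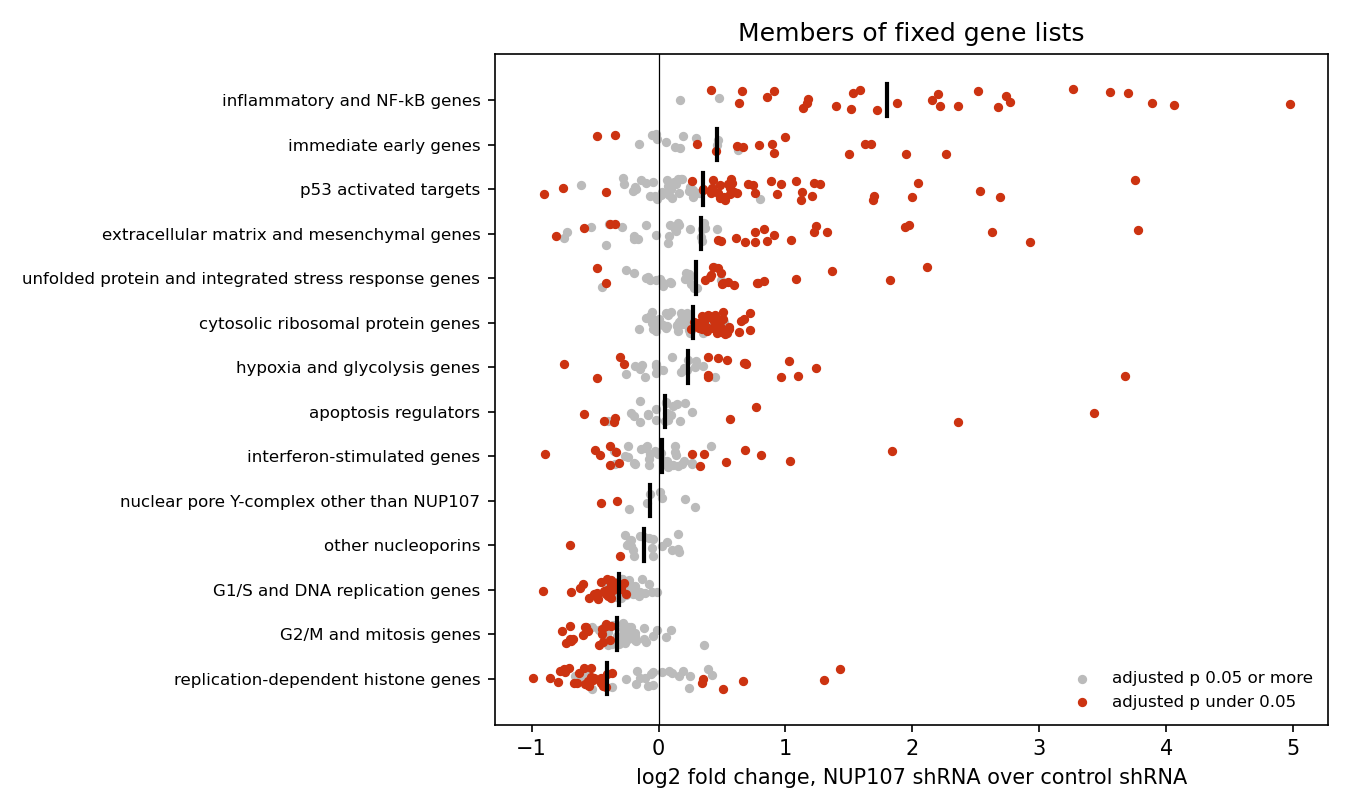
Fitted log2 fold change of NUP107 shRNA over control shRNA (horizontal axis) for the members of 14 fixed lists (vertical axis), 1 point per gene, in red where limma's adjusted p was under 0.05, with black bars at list medians. Inflammatory genes lay farthest to the right (median 1.80), with cell cycle and histone lists to the left of 0 and nuclear pore lists near 0; a few members such as CXCL8 and BMF were not well above background in the control arrays, so their points are fitted values and not measured folds.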

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

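The direction of the NUP107 fall and of the p53 target shift held under all alternatives run, with values from -0.998 to -0.722 and from 0.15 to 0.43, but how many genes passed depended on the processing. Higher genes numbered 5434 with a normexp background and 1197 under the spike-in scale, and lower genes 3673 under the array median and 4239 under the spike-in scale. With no filter on dim probes 332 were higher and 104 lower, and NUP107 (-0.80) had an adjusted p of 0.056. Without variance moderation 1 gene was higher and 1 lower (NUP107 -0.80, adjusted p = 0.090), and treat against a fold of 1.2 gave 835 and 430. The adjusted p of NUP107 ran from 7.7e-05 to 0.090 over its alternatives. Leaving out 1 array at a time, with the lone array taken to vary like the other group, gave 195 to 2869 higher genes, 36 to 2795 lower genes and NUP107 at -0.87 to -0.72. The smaller counts came without either control array (222 and 39 without replicate 1, 195 and 36 without replicate 2), when the spread rests on the NUP107 shRNA pair, and 37 of 160 named called genes then still passed in each case. With an estimated correlation, on 2 residual degrees of freedom, camera called 0 lists and the p53 target shift of 0.35 had an adjusted p of 0.79. Fry, which asks another question, called 1 list. Camera with the preset correlation called 9 to 11 lists under most alternatives, but 15 with a normexp background and 13 with no filter, against 10 in the main setting. Leaving out a NUP107 shRNA array leaves as many arrays as leaving out a control array, so the number of arrays alone cannot account for the smaller counts without a control array. Across probes, the log2 difference between the 2 arrays of a group had an SD of 0.255 for NUP107 shRNA and 0.193 for control. The causes of the differences between alternatives were not tested.

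The median of all genes was -0.01, and moved with the scale to -0.14 (array median) and -0.22 (spike-in), with the normexp background to 0.09, and was 0.10 over the 19724 genes kept with no filter. The normexp offset with the 75th percentile as scale gives a probe without signal 0.56 on the log2 scale by construction, so the sign of dim genes under it tests nothing. Of the lower calls under the spike-in scale, 2209 were those called with the 75th percentile, and 1144 of the higher calls were. The replicate block gave 2119 higher and 1749 lower genes, NUP107 a limma adjusted p of 0.018 and the p53 shift 0.35. Arrays of the same number shared little deviation (r = 0.06 across genes, 2 pairs). So few pairs cannot exclude pairing, and the labels do not say whether same-numbered arrays belong together. Of the 160 named called genes, 19 lost their call under the block, NUP37 and NUP205 among them. The slide block was not run, since there is 1 slide.

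Of 2880 comparisons of 171 named genes with their alternatives, 2199 kept their side of the threshold, 636 lost it, 18 gained it and 27 changed sign. With a normexp background, the sign changed for FAM226A (0.40), TGM6 (0.35), LUZP4 (0.36), LRP1B (0.18), TMEM244 (0.23), ECHDC3 (0.0444), COL4A4 (0.38), OR8B3 (0.34), GPR142 (0.30), H4C16 (0.0834), ID4 (0.21), HSPA1A (0.27), PMEPA1 (0.000603) and NUP98 (-0.0139). NUP98 and NUP133 were at -0.10 and -0.11 under the array median and at -0.18 and -0.19 under spike-in probes, where MDM4 was at -0.0732. With no filter FAM226A, on another probe, was at 0.78. With the mean of probes NUP98 was at -0.0820, AHCTF1 at 0.21 and NFIA at 0.12. Leaving out 1 array at a time, NUP98 ran from -0.0323 to 0.0827, NUP133 from -0.0524 to 0.0818 and AHCTF1 from -0.178 to 0.0455. Signal over background limits the dim genes most, with a median SE of 0.14 in the dimmest 20% of genes against 0.08 in the brightest.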

Other observations

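Marker genes of other brain and tissue cell types moved both ways, and none of these lists was called by camera in the main setting. The endothelial and pericyte list was called with a normexp background (median 0.48, adjusted p = 0.045, 5 higher and none lower). That setting gives a probe without signal 0.56 by construction, so this call and the higher counts of dim markers under it test nothing. Of 15 astrocyte and glial genes tested, ALDOC rose by 0.96 and SLC1A3 was at least 3.39-fold higher, while CPE, NFIA, CST3 and ID4 were lower (2 and 4 adjusted over the list alone). A second NFIA probe rose by 0.67, and ID4 changed sign under the normexp background. Of 16 neural stem and progenitor genes, JAG1, OLIG2, SALL2, HEY2 and NOTCH1 were higher (0.29 to 1.45) and NES and HEY1 were lower (7 and 3 adjusted over the list alone). NOTCH1 gave 0.04 on its other probe (adjusted p over all probes = 0.78). Of 11 neuron markers, SYP, SNAP25 and SYN1 were higher (0.85 to 1.57) and NEFM, ENO2, MAP2, TUBB3 and GAD1 lower (-0.68 to -0.30, with 3 and 6 adjusted over the list alone). GAD1 gave 0.08 on its other probe (adjusted p over all probes = 0.46). The neuron list had a median of -0.27 and a mean of 0.07, and the astrocyte (median 0.01) and epithelial (median -0.03) lists had medians of the opposite sign to their tests. MYRF was lower (-1.24) and MBP higher (0.94) among 6 oligodendrocyte markers. TMEM119 (1.36), CD14 (1.07) and CD163 (at least 4.97-fold) were higher among 12 microglia and immune markers, PECAM1 (1.71) and VWF (0.52) among 6 endothelial and pericyte markers, and KRT18 (0.79) and CDH16 (0.93) among 11 epithelial and kidney markers. SYP was above background on 1 of the 2 control arrays, and SALL2, MBP and ID4 on 1 of the 2 NUP107 shRNA arrays. Under the spike-in scale, higher and lower genes numbered 2 and 3 for epithelial, 3 and 3 for immune, 4 and 3 for stem cell, 1 and 2 for oligodendrocyte and 3 and 6 for neuron markers, and with a normexp background 6 and 0, 5 and 0, 8 and 2, 3 and 1, and 4 and 4, and for astrocyte genes 4 and 2. Without NUP107 shRNA replicate 1, they numbered 4 and 4 for astrocyte, 3 and 3 for neuron, 4 and 2 for immune and 3 and 3 for epithelial markers, and the endothelial median was 0.03. Without either control array 1 stem cell, 1 immune and 1 endothelial gene were higher and 1 oligodendrocyte gene was lower, and no gene of the astrocyte, neuron and epithelial lists passed. These genes were named after their values were seen, and ALDOC and ENO2 also stand on the hypoxia and glycolysis list.

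Housekeeping lists were not called in the main setting, and their counts stand beside 32.3% of all genes tested that were called. Of 73 oxidative phosphorylation genes, COX7C and ATP5F1E rose by 0.54 and 0.55 and 8 fell, of 50 ribosome biogenesis genes NPM1, NOB1 and UTP14A rose by 0.60, 0.31 and 0.28 and 7 fell, and of 46 lysosome and autophagy genes 6 rose, among them TFEB (1.16, and -0.05 on another probe) and SQSTM1 (0.73), and 8 fell, among them CTSK and GAA (-0.71 and -0.64). The other NPM1 probes gave 0.21 and 0.37 (adjusted p over all probes = 0.24 and 0.094). Among 24 cholesterol biosynthesis genes, TM7SF2, HMGCS1 and MVK rose (1.24, 0.56 and 0.34) and 6 fell. Among 34 heat shock and chaperone genes 6 rose, among them HSPA6 by 2.39 (0.72 on another probe) and DNAJB4 by 0.81, and CCT5, DNAJB1 and HSPA1A fell by 0.61, 0.35 and 0.44, where HSPA1A changed sign under the normexp background. The median fold changes of these 5 lists lay from -0.18 to 0.04 and their camera adjusted p from 0.20 to 0.70. With a normexp background camera called oxidative phosphorylation (adjusted p = 0.0015, 3 higher and 14 lower), ribosome biogenesis (0.020, 9 and 11), cholesterol biosynthesis (0.047, 6 and 10) and lysosome and autophagy genes (0.047, 8 and 14) downward, and with no filter it called the oxidative phosphorylation (0.045) and cholesterol lists (0.041). Camera sets a list against all other genes. The median of all genes was -0.01 in the main setting, 0.09 with normexp and 0.10 with no filter. List medians with normexp were -0.08, -0.07, -0.13 and -0.05, against -0.04, -0.05, -0.18 and -0.04 in the main setting. A rise of the other genes can thus contribute to these calls. Adjusted over the list alone, higher and lower genes numbered 0 and 0 for oxidative phosphorylation, 1 and 1 for ribosome biogenesis, 3 and 5 for lysosome and autophagy, 3 and 7 for cholesterol biosynthesis and 6 and 3 for heat shock genes. Under the spike-in scale the counts were 0 and 13, 1 and 13, 3 and 15, 1 and 12, and 2 and 6, in the same order. Oxidative phosphorylation had 3 and 3 without NUP107 shRNA replicate 1, and without replicate 2 it had 2 and 4, ribosome biogenesis 2 and 3 and lysosome and autophagy 3 and 6. Without control replicate 1 or control replicate 2, 1 heat shock gene was higher and no gene of the other 4 lists passed. Among noncoding RNAs, 3 of 3 ribosomal RNA genes rose, and of 14 small nucleolar RNA genes 6 rose and 1 fell, with a median of 0.40. Ribosomal RNA genes are repeated, and the RNA5-8SN5 probe cannot tell copies apart, so the 3 need not be separate results. These classes were counted in the main setting alone.

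Of the tests that follow, the one that scales ribosomal protein genes to the spike-in probes was chosen after its result had been seen, and the matching of random lists and the intervals were tightened after first values had been seen.

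The rise of p53 activated targets may reflect p53 activity after NUP107 knockdown, as a hypothesis found and tested on these data. A core of 24 tested members chosen as specific to p53, without CDKN1A, MDM2 and ANKRA2, held 14 that rose and none that fell. Its median of 0.45 lay at percentile 100 of 10000 random lists matched on signal (99th percentile 0.16). The core is part of a list that had risen as a whole, and it holds none of the 3 members that fell. Its specificity rests on that choice of members, and it was not compared with genes of other stress pathways. The test thus cannot decide whether members shared with those pathways account for the rise. The random draws also ignore correlation among list members. The full list (0.35, 99th percentile 0.08) also lay at percentile 100, which argues against a signal trend between arrays. Off-target effects of the hairpin stay open and untested. Correlation among p53 targets stays open too. Camera lost the call with an estimated correlation, but that test also rests on 2 residual degrees of freedom and so cannot decide it.

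The rise of ribosomal protein genes (median 0.27) lay at percentile 100 of random lists matched on signal, although such bright lists also had a median of 0.12, so a signal trend could account for part of it. For the brightest members the nearest genes outside the list can be mostly dimmer. This test thus cannot exclude such a trend as the whole cause. Quantile normalization, which evens out such trends, left a median of 0.08 (camera adjusted p = 0.039 with the preset correlation). In the main setting the list had an estimated correlation of 0.27, which the random lists ignore. Scaled to the spike-in probes it was 0.0681, with a standard error of 0.0852 for that scale between arrays. Whether these transcripts rose or others fell at a fixed amount of labelled RNA cannot be told apart, because 2 standard errors either side of it (-0.102 to 0.239) span both 0 and the 0.2 set for a rise. A biological change in ribosomal protein transcripts stays open as well.

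Among the 2209 lower genes, 278 had a fitted fall deeper than NUP107 itself, with a median percentile of control signal of 31.5 (95% bootstrap interval 28.1 to 36.0), where above 25 had been set against low signal of the NUP107 shRNA arrays as the whole cause and under 10 for it. It was 43.0 for the 209 measured on all arrays and 5.08 (3.37 to 7.40) for the other 69, a split that signal itself decides, so low signal stays open as the cause for these 69. Under the normexp background, which raises dim genes by construction, 174 of 276 passed as lower, 90 lay below NUP107, 82 lay above 0 and 60 passed as higher, 58 of these among the 69. Whether transcripts or single probes fell stays open for the 209 measured on all arrays, because 57 other probes of 42 of these had a median of -0.38 (95% bootstrap interval -0.50 to -0.24), not under the -0.8 set for a fall of the transcript and not wholly above the -0.4 set for single probes. Of these probes 47 lay under 0 and 28 under -0.4, and RAD1 gave -0.11 on its other probe.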
